A study of Mus musculus with 4 samples.

How the data were processed

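RNA of kidney and renal pelvis from MRL/MpJ and MRL/lpr mice was measured on 4 Agilent single-colour arrays, 1 per group, with 7 or 10 mice pooled per strain according to the series design text. All 4 arrays lay on 1 slide. The files held intensity values that, per the file headers, had been background-subtracted and detrended across each array by Agilent Feature Extraction but not scaled between arrays. Version 12.0.3.1 of that program is given in the submitters' processing notes. Spot means, local background medians and spot flags came from the same files, and probe coordinates refer to mm9.

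Each array had 62976 spots, 59305 of them not controls, for 56605 probes, of which 300 were printed in 10 spots. Spots flagged as outliers (121, 89, 90 and 95 on the MRL/MpJ kidney, MRL/lpr kidney, MRL/MpJ renal pelvis and MRL/lpr renal pelvis arrays) and control spots were left out, and no spot was saturated. Processed signals were put on a log2 scale, averaged over the spots of a probe, and set relative to the 75th percentile of each array (337.5, 356.4, 393.2 and 480.9 before scaling). A probe counted as above background where at least 50% of its kept spots were flagged well above background, which held for 36142, 36486, 37006 and 39053 probes and 17267, 17407, 17674 and 18295 genes. Normalised units quoted in the text place all arrays on 1 common 75th percentile.

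Probes were given gene names by RefSeq accession (33767), by the symbol of the array design (9866) or by a unique older symbol (310). The remaining 12662 had no name and entered no gene comparison. A gene was read by its brightest probe over the 4 arrays. This gave 24841 genes, 11378 of them with several probes and 16558 above background on all 4 arrays. Without a genome, probe positions within transcripts were not determined.

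There were 5 comparisons: strain in each tissue, tissue in each strain, and the strain difference in renal pelvis minus that in kidney. A gene was measured where it was above background on both arrays (all 4 for the last), and called at 2-fold. Genes above background on 1 array were given a bound against the signal floor of the other. No test was made, as each comparison had 1 array on each side. A fit of strain and tissue effects without their interaction, with 1 residual degree of freedom, was not run. The 41 gene lists (504 of 507 genes were on the array) were written before the data were examined, and 1 more, of brown fat genes, afterwards. A list median used members above background on at least 1 array of the comparison. It was placed among 10000 random lists matched in 20 bins of brightness, and its 95% interval came from 2000 bootstrap draws. Lists with fewer than 3 measured members (Fas and its ligand, sex genes) were read gene by gene.

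Genes were named by a rule fixed in advance: the 10 highest and 10 lowest of each comparison with a gene symbol in place of a clone name, the 5 highest bounds each way, Fas and Fasl, and up to 4 members of each list with the largest difference. Genes named outside the rule are said to be so. From those the rule picked, 7 were left out of the text and of the counts of named differences, by request and not for their values. Alternatives fixed in advance were normexp background correction (offset 50), quantile normalization, a 75th percentile over probes above background on all 4 arrays, the mean of a gene's probes, other filters on dim probes and members, and a 4-fold rule. Scaling on 8 spike-in probes and raising values to the array floor were added after the data had been seen. The computation of the calls was checked on simulated data whose noise was that of replicate spots only. All genes set 2.5-, 4- or 8-fold apart and none set 1.5-fold apart were called at 2-fold. With noise so small this outcome was fixed by the design, and it does not show how reliable the calls on real arrays are. Work was done in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.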

Results

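The series held 4 single-colour expression arrays, 1 for each pairing of strain and tissue. Per the labels, RNA came from kidney and renal pelvis of MRL/MpJ mice and of MRL/lpr mice, which carry the lpr allele of the death receptor gene Fas, at 6 months of age. Each array received 1 RNA pool, from 7 MRL/MpJ or 10 MRL/lpr mice. With 1 array per group there was no replicate check, so that no p-value is given and a difference between arrays includes any chance difference between pools. Differences are given as log2 values, MRL/lpr minus MRL/MpJ or renal pelvis minus kidney. A gene was counted as higher or lower where its 2 arrays lay at least 2-fold apart. A gene above background on only 1 array of a pair was counted apart, by the smallest difference that the signal floor of the other array allowed (a bound). Rankings of single genes leave out bounds and genes known by clone names. The gene lists given here, the comparisons and the size rule were fixed before the data were examined. Ranges in parentheses after a list median are 95% bootstrap intervals over its genes, and percentiles place that median among 10000 random lists of similar brightness. Both describe these arrays only.

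The 2 Fas probes read differently. The brightest Fas probe, near the 3' end of the gene (chromosome 19, 34402164 to 34402223, mm9), read 512 normalised units on the MRL/MpJ kidney array and 495 on the MRL/lpr kidney array, with 556 and 1086 on the renal pelvis arrays, log2 differences of -0.05 and 0.97. A Fas probe for a shorter transcript (chromosome 19, 34383733 to 34383792) was above background only on the MRL/lpr arrays, by at least 1.22-fold in kidney and 2.41-fold in renal pelvis. The lpr allele is known as an insertion within Fas that cuts its transcripts short. The dim signal of the other probe went with the strain labels, and the 3' signal, which did not fall on the MRL/lpr arrays, did not. Where the probes lie relative to the insertion was not determined, and the strain names used here are those of the labels. The ligand gene Fasl was above background on the MRL/lpr kidney array alone (log2 difference at least 4.82) and was higher on the MRL/lpr renal pelvis array (5.30).

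All mice were labelled male, but transcripts that mark sex read otherwise. Xist, the RNA of the silenced X chromosome in female cells (chromosome X, 100662174 to 100662233), was above background on all 4 arrays, at 533, 532, 441 and 434 units in the order MRL/MpJ kidney, MRL/lpr kidney, MRL/MpJ renal pelvis and MRL/lpr renal pelvis. Of 13 probes for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, 12 were at background on all 4 arrays. The exception was 1 of 6 Kdm5d probes, at 37.5, 30.3, 30.5 and 36.1 units in the same order. These values argue against the male label for all 4 pools. Since the 1 Kdm5d probe was not explained, no sex is assigned here, also for the male kidney genes named here.

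In kidney, transcripts of T cells, cytotoxic cells, macrophages and antigen-presenting cells were higher on the MRL/lpr array, together with the chemokines that draw such cells. Tubule transcripts lay lower by less than 2-fold in most cases, while podocyte transcripts did not lie lower. Among genes above background on both arrays, the largest differences were those of Ccl8, a chemokine for monocytes (6.91, at 112 and 13441 units), the chitinase-like protein gene Chil1 (6.05), and Ubd, a ubiquitin-like protein induced by interferon gamma (5.92). Next came the T cell chemokine Cxcl9 (5.81), the B cell chemokine Cxcl13 (5.54), the lymphocyte membrane gene Ms4a4b (5.49), Ccl5 (5.31) and the interferon-induced GTPase Iigp1 (5.28). Klra17 (5.66) belongs to a multigene family whose probes may cross-hybridise. Above background on the MRL/lpr kidney array alone were the cell cycle inhibitor gene Cdkn2a (at least 6.51), the granzyme gene Gzmk (6.28), Eomes, a transcription factor of cytotoxic cells (5.74), the inhibitory receptor gene Pdcd1 (5.56) and Acod1, which makes itaconate in macrophages (5.53).

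Among lymphocyte lists, 17 of 19 measured T cell genes were at least 2-fold higher, bounds included, with a median of 4.03 (3.1 to 4.39). They included Cd3g (4.75), Cd3d (4.74) and Cd2 (4.68). The 2 within 2-fold, named outside the rule, were the co-receptor genes Cd4 (0.55) and Cd8a (0.73). The cytotoxic and natural killer list had 10 of 11 genes higher and a median of 3.63 (2.70 to 5.31), with Nkg7 (4.94) beside Gzmk and Eomes. Of the B cell genes 10 of 14 were higher (median 2.87 (0.87 to 3.36)), among them the follicle-homing receptor gene Cxcr5 (at least 4.70) and Tnfrsf13c (at least 4.09). Plasma cell genes stood at 9 of 12 higher (median 2.15 (0.85 to 3.19)), led by Pou2af1 (4.44), Mzb1 (3.68), Irf4 (3.55) and the antibody joining chain gene Jchain (2.83). For genes of lymphoid structures, 9 of 15 were higher (median 2.32 (0.09 to 3.30)), with the homing receptor gene Ccr7 at 3.33.

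Myeloid and antigen presentation genes lay on the same side. Macrophage genes were higher in 14 of 18 cases (median 2.75 (1.67 to 3.21)), with the antibody receptor gene Fcgr1 (4.56), Clec7a (4.30) and Cd68 (3.32). Every measured gene of the class II list was higher (9 of 9, median 3.58 (2.92 to 3.67)), including the invariant chain gene Cd74 (3.79), H2-Oa (3.67), H2-Ab1 (3.62) and their regulator Ciita (3.63). Dendritic cell genes were higher in 7 of 11 cases and lower in 1 (median 2.45 (-0.048 to 3.33); Itgax 4.23) and neutrophil genes in 5 of 11 (median 1.87 (0.053 to 2.15); S100a8 2.42, S100a9 2.08). Inflammatory chemokines stood at 11 of 15 (median 3.40 (1.41 to 4.66)) and inflammatory cytokines at 8 of 12 (median 1.27 (0.93 to 3.1)), the latter with Ifng (at least 5.34) and Il1b (2.34). Interferon-stimulated genes of type I stood at 18 of 22 (median 1.69 (1.46 to 2.26)), with Mx1 (3.47). Complement genes were higher in 9 of 15 cases (median 1.24 (0.53 to 1.38); C3 2.85, C4b 2.5), toll-like receptor genes in 6 of 13 (0.84 (0.28 to 1.62); Tlr8 3.25) and adhesion genes in 6 of 8 (2.35 (0.90 to 3.24); Vcam1 2.66, Itga4 3.24).

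Nephron lists lay below the other genes of similar brightness, with most members within 2-fold. Proximal tubule genes had a median of -0.81 (-0.85 to -0.68) and 3 of 21 were lower: the amino acid transporter gene Slc7a13 (-2.49) and the endocytic receptor genes Cubn (-1.21) and Lrp2 (-1.09). Medians were -0.67 (-0.78 to -0.63) for the loop of Henle (Egf -0.98), -0.77 (-1.01 to -0.54) for the distal convoluted tubule (Calb1 (-1.21), Pvalb (-1.01)), -0.56 (-0.75 to -0.36) for principal cells, where the water channel gene Aqp4 was lower (-1.72), and -0.73 (-0.79 to -0.54) for intercalated cells (Rhcg -0.93). Fatty acid oxidation genes stood at -0.52 (-0.60 to -0.48) and drug and steroid metabolism genes of male kidney at -0.72 (-0.96 to -0.01), with Akr1c18 (-1.79) and Cyp2e1 (-1.37) lower. Podocyte genes had a median of 0.12 (-0.094 to 0.63), percentile 98.3, and 12 of 12 lay within 2-fold. The renin gene Ren1 was lower (-1.43) in a mesangial and juxtaglomerular list with a median of -0.25 (-0.66 to 0.53).

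Kidney injury genes were higher in 7 of 13 cases, with a median of 1.39 (0.90 to 2.38): Krt20 (3.57), Cd44 (3.34), the iron-binding defence gene Lcn2 (2.89) and the protease inhibitor gene Timp1 (2.38). The other 6 lay within 2-fold, among them, named outside the rule, Havcr1 (-0.87). Krt20 is also a member of the umbrella cell list. Cell cycle genes were higher in 10 of 13 cases (median 1.86 (1.29 to 1.93); Top2a 2.60, Mki67 2.18), matrix genes in 7 of 15 (median 1.0 (0.72 to 1.57); Thy1 3.1, Col1a1 1.57) and antimicrobial genes in 8 of 16 (median 1.48 (0.10 to 2.30); Saa3 2.86). Thy1 is also a member of the T cell list. Of the umbrella cell genes 4 of 8 were lower and 1, Krt20, higher (median -0.82 (-1.47 to 0.28); Upk2 -2.17, Upk1b -1.47). Of the basal and intermediate urothelial genes 3 of 15 were lower, with Krt14 (-1.96) and Krt15 (-1.68), but the list median was -0.071 (-0.67 to 0.45). These are urothelial genes, read here in kidney RNA. Further medians were those of junction genes (-0.35 (-0.42 to -0.05)), smooth muscle (0.54 (-0.14 to 0.63)), endothelium (-0.24 (-0.42 to -0.065)), lymphatic endothelium (-0.17 (-0.75 to 0.61)) and adipocytes (-0.27 (-0.85 to 0.22)). Nerve stood at 0.22 (-0.57 to 0.77), adrenal cortex at -0.19 (-0.94 to 0.59), red cells at -0.21 (-0.23 to -0.089) and housekeeping genes at -0.16 (-0.37 to 0.059).

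The lowest named genes on the MRL/lpr kidney array were Igfbp5, which binds insulin-like growth factors (-4.22, at 8047 and 431 units; chromosome 1, 72904829 to 72904888), the basement membrane netrin gene Ntn4 (-2.75), Ceacam13 (-2.74), the glucocorticoid-binding globulin gene Serpina6 (-2.69), Slc7a13 (-2.49), the endothelial proteoglycan gene Esm1 (-2.29), Albfm1 (-2.26) and the organic anion transporter gene Slc22a26 (-2.17), whose probes may also read its close paralogs. In all, 1083 of 16784 measured genes were higher and 324 lower, 485 and 17 of them by 4-fold. Bounds added 276 higher and 68 lower. The median gene lay at -0.18, and relative to it 1286 were higher and 175 lower. With normexp background correction 128 genes were lower, and the medians of the cytotoxic and cell cycle lists were 1.87 and 0.97. Under quantile normalization, those of fatty acid oxidation and red cells were -0.30 and -0.053.

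**Figure D1:**
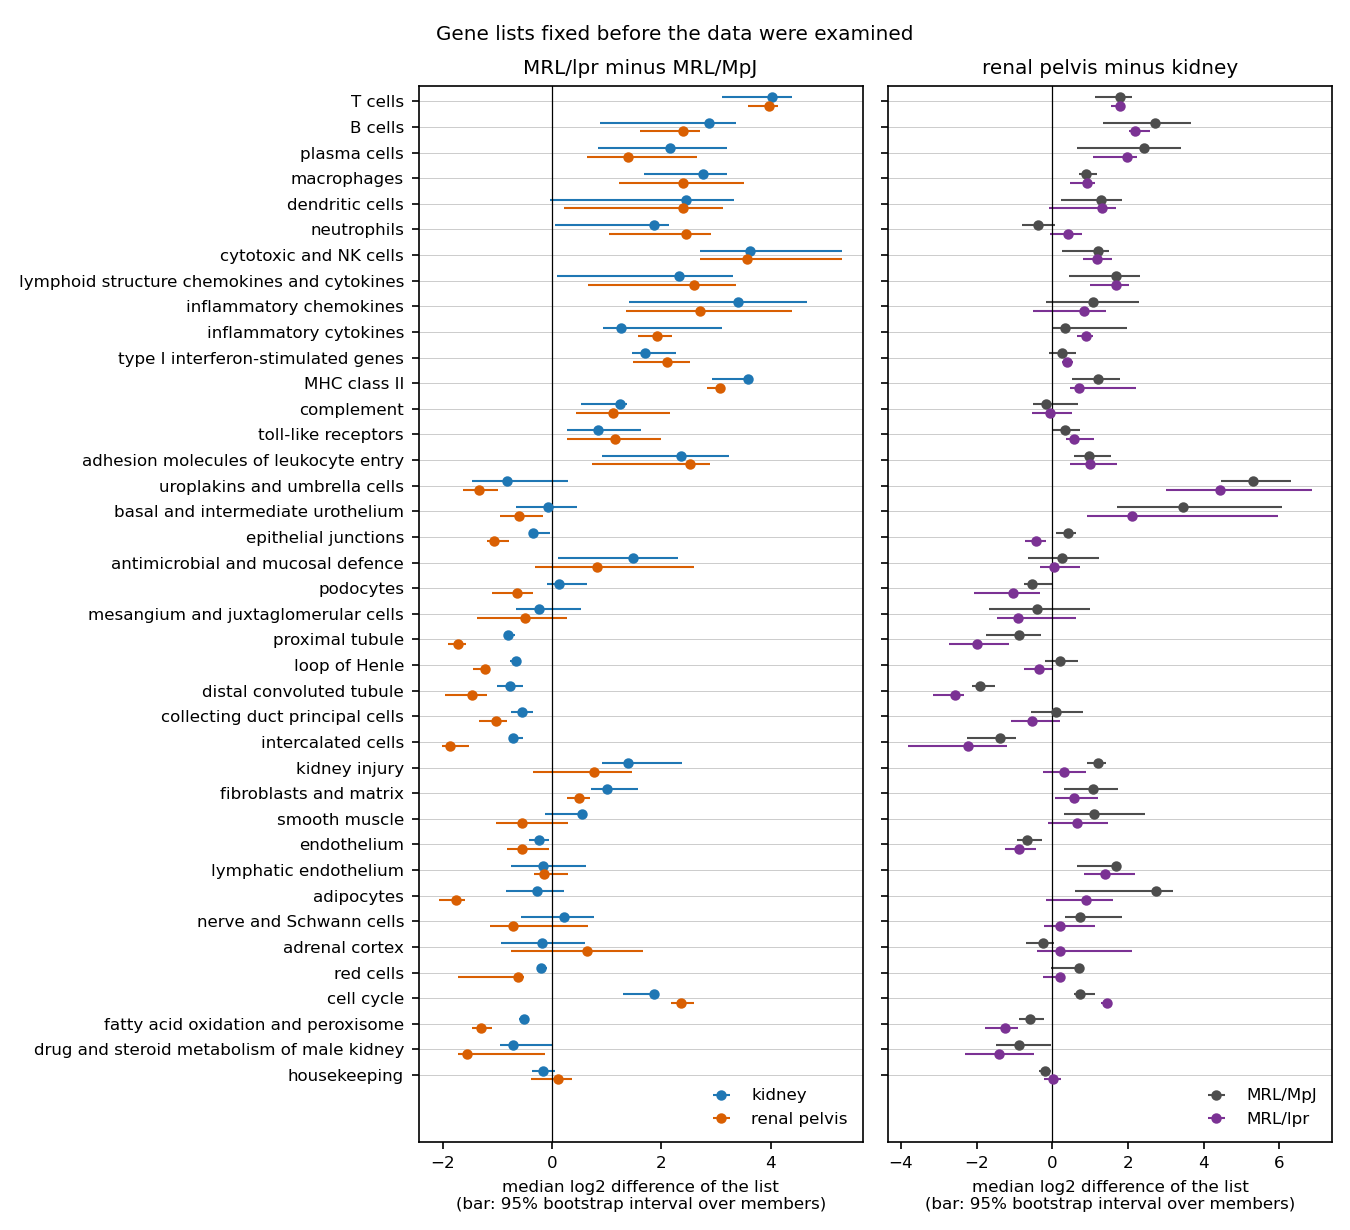
Median log2 difference (horizontal axis) of each gene list (rows), MRL/lpr minus MRL/MpJ on the left and renal pelvis minus kidney on the right, with 95% bootstrap intervals over genes as bars. Immune lists lay to the right in each strain comparison (T cells 4.03 in kidney and 3.96 in renal pelvis), and tubule lists to the left (proximal tubule -0.81 and -1.72).

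In renal pelvis, immune transcripts were again higher on the MRL/lpr array, and lists of every tubule segment, of umbrella cells, of epithelial junctions and of adipocytes were lower. Of genes above background on both arrays, Chil1 had the largest difference (7.41, at 58.6 and 9982 units), and the acute-phase gene Saa3 followed it (6.61). Next came Eomes (6.49), Gzmk (5.98), the transcription factor gene Myb (5.91), Clec4e, a receptor for microbial glycolipids (5.74), the coagulation factor gene F10 (5.73), the cystatin gene Cst7 (5.67), the lymphocyte adaptor gene Sh2d1a (5.67) and Ifng (5.59). Above background on the MRL/lpr array alone were the granzyme gene Gzmb (at least 4.98), Wfdc21 (4.54) and the ADP-ribosyltransferase gene Art2a (4.35). So were Ifi214 (5.35) and Gbp2b (4.48), 2 interferon-induced genes of families with close paralogs.

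All 20 measured T cell genes were higher, with a median of 3.96 (3.57 to 4.13), among them Pdcd1 (4.55), Cd27 (4.53), Zap70 (4.45) and Cd3g (4.41). Cytotoxic genes were higher in 11 of 12 cases (median 3.57 (2.70 to 5.31); Nkg7 5.18). So were B cell genes in 12 of 15 (median 2.40 (1.60 to 2.71); Cxcr5 3.91, Spib 2.71) and plasma cell genes in 8 of 13 (median 1.39 (0.64 to 2.65); Pou2af1 3.02, Prdm1 2.65). Macrophage genes were higher in 13 of 18 cases and lower in 1 (median 2.40 (1.21 to 3.52); Clec7a 4.73, C1qa 3.76). Dendritic cell genes were higher in 8 of 11 and lower in 1 (median 2.40 (0.22 to 3.13); Itgax 4.70) and neutrophil genes in 8 of 12 (median 2.45 (1.04 to 2.90); S100a8 3.80, Mpo 3.01). The class II list stood at 9 of 9 (median 3.07 (2.84 to 3.17); H2-Aa 3.52, Cd74 3.30).

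Inflammatory chemokines were higher in 10 of 15 cases (median 2.71 (1.34 to 4.39); Cxcl9 5.17, Ccl4 5.08, Ccl8 4.96), and genes of lymphoid structures in 8 of 16 (median 2.60 (0.66 to 3.36); Cxcl13 4.15). Inflammatory cytokines were higher in 11 of 13 cases (median 1.93 (1.57 to 2.18)), with Il1b (3.00), the epithelial alarm cytokine gene Il33 (2.30) and Il10 (2.18). Type I interferon-stimulated genes stood at 18 of 22 (median 2.10 (1.49 to 2.52); Mx1 3.82, Zbp1 3.07). Complement genes stood at 8 of 15 (median 1.12 (0.43 to 2.15); C4b 2.96), toll-like receptors at 8 of 13 (median 1.15 (0.27 to 2.00); Tlr8 3.05, Tlr13 2.01). Adhesion genes stood at 6 of 9 (median 2.53 (0.73 to 2.88); Itgb2 2.79) and cell cycle genes at 12 of 14 (median 2.36 (2.17 to 2.60); Aurkb 2.60, Mki67 2.76).

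Umbrella cell and junction genes lay lower on the MRL/lpr renal pelvis array, and most basal and intermediate urothelial genes lay within 2-fold. Of the umbrella cell genes 7 of 10 were lower and none higher (median -1.34 (-1.64 to -1.0)): the plaque protein genes Upk1a (-1.74) and Upk3b (-1.39), Snx31 (-1.67) and Krt20 (-1.64). Basal and intermediate urothelial genes were lower in 4 of 16 cases (median -0.60 (-0.95 to -0.18); Shh -1.20, Krt7 -1.08). The other 12 lay within 2-fold, among them, named outside the rule, Krt14 (-0.032) and Krt15 (-0.18). Junction genes were lower in 12 of 20 cases (median -1.07 (-1.20 to -0.80)), with the claudin genes Cldn19 (-1.65) and Cldn2 (-1.33) and the tight junction gene Marveld3 (-1.61). The other 8 lay within 2-fold, among them, named outside the rule, Cldn4 (-0.27) and Cldn7 (-0.57). The umbrella cell and junction lists moved with the tubule lists, and the basal and intermediate list by less. For the junction list this was partly built in, as it shares members with the loop of Henle list, Cldn19 among them. Proximal tubule genes were lower in 21 of 21 cases (median -1.72 (-1.91 to -1.57); Slc22a8 (-1.98), Slc5a12 (-1.96)). Loop of Henle genes were lower in 9 of 10 (-1.23 (-1.45 to -1.14); Umod -1.28), distal convoluted tubule in 6 of 7 (-1.48 (-1.96 to -1.19); Slc12a3 -1.96). Principal cell genes were lower in 5 of 10 (-1.03 (-1.33 to -0.82); Avpr2 -1.37) and intercalated cells in 10 of 11 (-1.87 (-2.02 to -1.52); Slc26a4 -2.58, Foxi1 -2.02). Fatty acid oxidation genes were lower in 13 of 16 cases (-1.30 (-1.47 to -1.11); Ehhadh -1.90, Ppara -1.79) and male kidney metabolism genes in 8 of 14 (-1.57 (-1.73 to -0.13); Ugt2b38 -2.22, of a family that may cross-hybridise).

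Fat genes stood apart on the MRL/MpJ renal pelvis array. Of the adipocyte genes 9 of 10 were lower on the MRL/lpr array (median -1.77 (-2.08 to -1.59)), and Ucp1, the uncoupling protein of brown fat, had the lowest difference of genes above background on both arrays (-6.86; 1121 and 9.67 units; chromosome 8, 85821788 to 85821847), with the lipid droplet genes Cidea (-3.67) and Plin1 (-2.08) and the lipase gene Lpl (-2.08) also lower. Other low genes were Igfbp5 (-4.74), the matrix gene Aspn (-3.96), Fcrls (-3.87), Ntn4 (-3.32), Ceacam13 (-3.26), Serpina6 (-3.20) and the sulfate transporter gene Slc13a4 (-3.17). Pus7 (-3.67) had a second probe at -0.48. On the MRL/MpJ array alone were Crtac1 (lower by at least 4.54), Abca12 (3.37), the noradrenaline-making enzyme gene Dbh (3.29) and Il17f (3.12), beside the pheromone receptor gene Vmn1r215 (4.53), read by 1 probe of a large family.

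Further lists gave smaller medians. Podocyte genes were lower in 4 of 12 cases and higher in 1 (median -0.64 (-1.10 to -0.36); Podxl -1.29). Matrix genes had a median of 0.48 (0.28 to 0.70), with 2 of 15 higher, Thy1 (2.88) and Fap (2.59). Of these, Thy1 is also a member of the T cell list. Kidney injury genes had a median of 0.76 (-0.34 to 1.47) with Cd44 (2.70) and Vim (1.98) higher and Havcr1 (-1.93) lower, and antimicrobial genes 0.82 (-0.32 to 2.60). Sprr2f (5.02) belongs to a family of near-identical genes. Smooth muscle stood at -0.56 (-1.03 to 0.29) with Cnn1 (-1.61) lower, endothelium at -0.56 (-0.83 to -0.053) with Flt1 (-1.36) lower, nerve at -0.73 (-1.14 to 0.65) with Ngfr (2.28) higher, and red cells at -0.62 (-1.72 to -0.52). Mesangial (-0.49 (-1.39 to 0.26)), lymphatic endothelial (-0.14 (-0.33 to 0.29)), adrenal (0.64 (-0.76 to 1.66)) and housekeeping genes (0.11 (-0.40 to 0.36)) had intervals that included 0.

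In all, 1732 of 17334 measured genes were higher and 2457 lower, 828 and 159 of them by 4-fold, and bounds added 298 and 174. The median gene lay at -0.18, and relative to it 2037 were higher and 1724 lower. With normexp background correction 1540 genes were lower, and the medians of the neutrophil and inflammatory cytokine lists were 0.52 and 1.22.

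With the main processing, most immune lists had strain differences of similar size in the 2 tissues. Most tubule lists and those of podocytes, junctions and fat lay further down in renal pelvis. With normexp background correction, the T cell and B cell lists lay further up in renal pelvis (0.77 and 0.66). Across 16558 genes above background on all 4 arrays, the 2 differences, which share no array, had a Pearson r of 0.84 and a Spearman rho of 0.76, and 78.9% of genes had the same sign. Of 1074 genes higher in kidney and 1503 higher in renal pelvis 943 were shared, against 97.5 if independent, and of 305 and 2360 lower genes 260 were shared, against 43.5. Both tissues of a strain are read as coming from the same mice, so a chance difference between the pools enters both strain differences, which the values for independence leave out. Opposite in direction at 2-fold were 2 genes, picked out after their values were seen: the keratin gene Krt20, at 3.57 in kidney and -1.64 in renal pelvis, and Igfbp2, whose product binds insulin-like growth factors, at 1.01 and -1.25. The probe positions were chromosome 11, 99289776 to 99289835 and chromosome 1, 72898677 to 72898736.

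**Figure D2:**
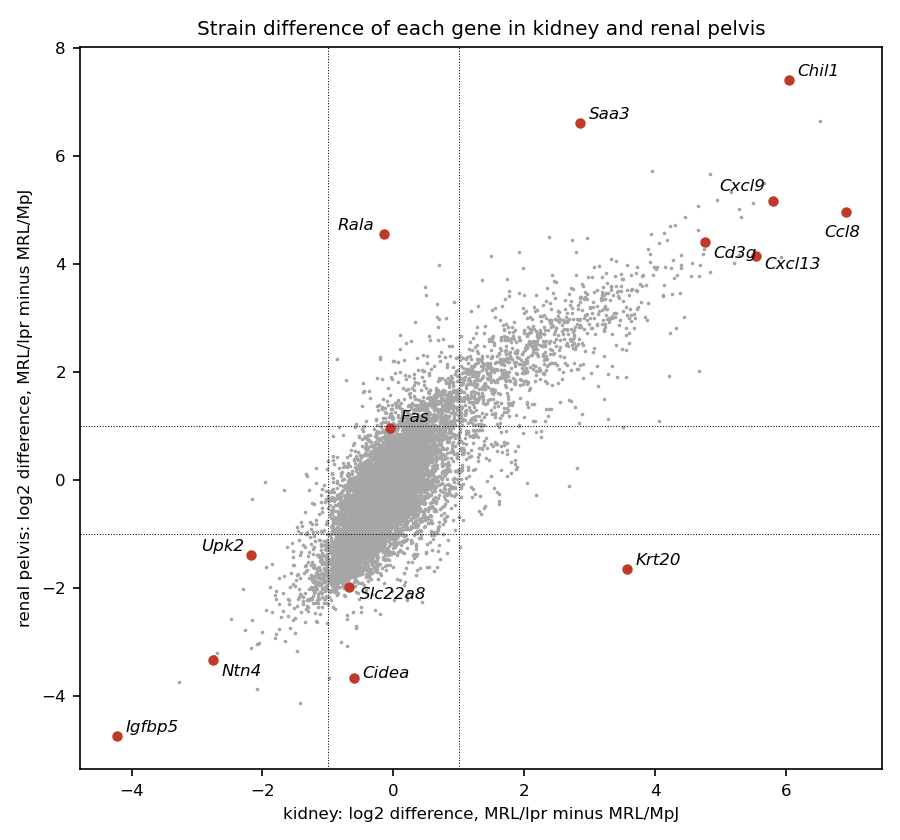
Log2 difference of MRL/lpr minus MRL/MpJ in kidney (horizontal axis) against the same in renal pelvis (vertical axis), 1 point per gene above background on all 4 arrays. Cd3g (4.75 and 4.41) lay near the diagonal, while Krt20 (3.57 and -1.64) and Cidea (renal pelvis -3.67) lay off it.

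Taking the strain difference in renal pelvis minus that in kidney, T cell genes had a median of -0.11 (-0.22 to 0.40), although Cd8a (1.63), Cd4 (1.40) and Cd3e (1.22) were further apart in renal pelvis. List medians included members not above background on all 4 arrays, 4 of 20 for T cells and 7 of 15 for B cells. Other immune lists had intervals that included 0: B cells (-0.27), plasma cells (0.049; Jchain -1.77), macrophages (-0.14; Cd163 -1.32) and dendritic cells (-0.15). With members above background on all 4 arrays only, the B cell median was 0.13. Intervals also included 0 for class II genes (-0.40), complement (0.11), toll-like receptors (0.13), adhesion (0.025), lymphoid structures (0.15; Cxcl13 -1.40), inflammatory cytokines (0.14), cytotoxic genes (0.33; Prf1 1.57) and type I interferon-stimulated genes (0.18). Neutrophil (0.63 (0.30 to 1.25); Mpo 2.35, S100a8 1.38) and cell cycle genes (0.56 (0.38 to 0.67)) lay further up in renal pelvis. Inflammatory chemokines stood at -0.50 (-1.42 to 0.023), with Cxcl1 (-2.05), Ccl8 (-1.95) and Ccl2 (-1.42) further up in kidney.

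Tubule lists lay further down in renal pelvis: proximal tubule -0.92 (-1.04 to -0.84) with Slc22a6 (-1.37) and Slc22a12 (-1.26), loop of Henle -0.56 (-0.70 to -0.50), principal cells -0.57 (-0.67 to -0.47) and intercalated cells -1.07 (-1.33 to -0.79) with Slc26a4 (-1.87). The distal convoluted tubule stood at -0.74 (-0.95 to 0.0056), with Slc12a3 (-1.33). Also further down, most by less than 2-fold, were podocytes (-0.71 (-1.22 to -0.51); Nphs1 -1.49), junctions (-0.76 (-0.82 to -0.68); Cldn3 -1.19), smooth muscle (-0.72 (-1.01 to -0.42); Cnn1 -2.16) and endothelium (-0.42 (-0.56 to -0.039)). So were adipocytes (-1.28 (-2.28 to -1.07); Plin1 -2.30, Cfd -2.28) and kidney injury genes (-0.80 (-1.36 to -0.29); Sox9 -1.90, Spp1 -1.36), as well as fatty acid oxidation (-0.73 (-0.88 to -0.55)), male kidney metabolism (-0.57 (-0.93 to -0.34)) and red cell genes (-0.50 (-1.08 to -0.29)). Umbrella cells stood at -0.32 (-1.44 to 0.22) and basal urothelium at -0.51 (-0.86 to 0.15). There, Krt14 (1.93) and Krt15 (1.5) lay on the other side from Sprr1a (-1.70) and Krt19 (-1.33). Medians were -0.30 for matrix (Lox -1.67), -0.28 for antimicrobial genes (Saa1 2.04), -0.30 for mesangium and 0.19 for lymphatic endothelium. Nerve stood at -0.51, adrenal cortex at 0.83 and housekeeping genes at 0.21.

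Among single genes with the largest gap upward in renal pelvis were Saa3 (3.75), the kallikrein gene Klk4 (3.30), Ido1, which breaks down tryptophan (2.67) and the fatty acid transporter gene Slc27a1 (2.49). Rala (4.70) rested on 1 probe that was dim on the MRL/MpJ renal pelvis array alone, and Mapkapk3 (2.59) had a second probe at 0.33. Those furthest downward were Krt20 (-5.21), Cidea (-3.07), Sidt1 (-2.97), the haptoglobin gene Hp (-2.79), the metalloprotease gene Adamdec1 (-2.64), Ly6d (-2.59) and the cathepsin gene Ctse (-2.52). In all, 332 of 16558 genes were at least 2-fold further up in renal pelvis and 712 further down (31.8% up). With normexp background correction these were 216 and 206 (51.2% up), and the T cell, B cell and neutrophil medians were 0.77, 0.66 and 0.27.

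Between tissues of MRL/MpJ mice, urothelial genes marked the renal pelvis array. Fat, lymphocyte, lymphatic and smooth muscle genes were also higher there, while proximal and distal tubule and intercalated cell genes were higher in kidney. Among genes above background on both arrays, the uroplakin gene Upk3a had the largest difference (7.24, at 104 and 15606 units; chromosome 15, 84851819 to 84852720), with Upk1b (6.34) and Upk2 (6.31), the keratin genes Krt15 (6.99), Krt5 (6.83) and Krt14 (6.07), the cornified envelope gene Sprr1a (6.35), Ly6d (6.30) and the membrane protease gene Tmprss13 (5.93). Sprr2a3 (6.93) has near-identical paralogs. On the renal pelvis array alone were the urothelial transcription factor gene Foxa1 (at least 7.32), Fer1l4 (6.93), Ucp1 (6.68), Ttc6 (5.84) and the calpain gene Capn13 (5.73).

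All 10 umbrella cell genes were higher in renal pelvis (median 5.31 (4.46 to 6.31); Psca 5.59), as were 14 of 16 basal and intermediate urothelial genes (median 3.46 (1.72 to 6.07)). Adipocyte genes were higher in 7 of 10 cases (median 2.75 (0.59 to 3.19); Cfd 3.30, Plin1 3.19, Adipoq 2.85). Smooth muscle genes were higher in 6 of 11 (median 1.11 (0.31 to 2.46); Cnn1 4.16, Myh11 2.54), matrix genes in 9 of 15 (median 1.08 (0.30 to 1.73); Postn 2.67, Lum 2.36). Lymphatic endothelial genes were higher in 5 of 7 (median 1.67 (0.65 to 1.77); Pdpn 1.69). Kidney injury genes were higher in 9 of 14 cases (median 1.19 (0.91 to 1.42)). Among them was Krt20 (4.76), which is also counted in the umbrella cell list. The antimicrobial list had a median of 0.26 (-0.65 to 1.23), with Reg3g above background in renal pelvis alone (at least 5.01), Lcn2 at 1.42 and Slpi at 3.75, whose second probe read 0.22.

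Lymphocyte genes were higher in renal pelvis in mice of this strain too. Of the T cell genes 13 of 18 were higher and 1 lower (median 1.78 (1.12 to 2.10); Cd2 2.79, Cd3d 2.31), and of the B cell genes 9 of 14 were (median 2.71 (1.34 to 3.65)). Ms4a1 stood at 4.02 with a second probe at -0.79. Higher were 8 of 12 plasma cell genes (median 2.44 (0.66 to 3.41); Jchain 3.41) and 9 of 13 lymphoid structure genes (median 1.67 (0.45 to 2.32); Ltb 2.33, Cxcl13 2.80). Class II genes stood at 5 of 9 (median 1.21 (0.52 to 1.78)), inflammatory chemokines at 8 of 14 (median 1.08 (-0.15 to 2.30); Ccl8 4.04) and cytotoxic genes at 5 of 10 (median 1.21 (0.27 to 1.49)). Dendritic cell genes stood at 5 of 10 (median 1.30 (0.22 to 1.85)), macrophages at 7 of 17 (median 0.89 (0.71 to 1.18); Aif1 1.42) and adhesion genes at 4 of 8 (median 0.96 (0.58 to 1.55)). Smaller medians were those of neutrophils (-0.38), inflammatory cytokines (0.32), type I interferon-stimulated genes (0.26), complement (-0.16) and toll-like receptors (0.35; Tlr5 2.73). Cell cycle stood at 0.73, nerve at 0.73 (S100b 2.10), red cells at 0.71 and junctions at 0.41 (Cldn4 1.58).

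Kidney markers differed by segment. Distal convoluted tubule genes were lower in renal pelvis in 7 of 8 cases (median -1.90 (-2.12 to -1.53); Trpv5 -2.43, Pvalb -2.12), intercalated cell genes in 8 of 11 (-1.38 (-2.26 to -0.95); Hmx2 -3.01, Slc26a4 -2.68) and proximal tubule genes in 9 of 21 (-0.88 (-1.76 to -0.30); Slc22a8 -2.53, Slc5a2 -2.19). Loop of Henle (0.21 (-0.20 to 0.69)) and principal cell genes (0.087 (-0.55 to 0.82)) did not lie lower as lists. Medians were -0.54 (-0.74 to 0.024) for podocytes, -0.67 (-0.93 to -0.28) for endothelium (Kdr -1.39), -0.40 (-1.66 to 0.99) for mesangium (Ren1 -2.42), -0.59 (-0.87 to -0.21) for fatty acid oxidation (Cyp4a14 -1.49) and -0.87 (-1.48 to -0.032) for male kidney metabolism (Cyp4b1 -2.17). Adrenal cortex stood at -0.24 and housekeeping genes at -0.18. Single low genes were the methyltransferase gene Bhmt (-2.72), the carrier gene Slc16a14 (-2.75), Azgp1 (-2.65), the lectin gene Mbl2 (-2.65) and Insrr (-2.62). The lowest value of a gene above background on both arrays, that of Rala (-4.49), rested on 1 probe, dim on this renal pelvis array only (106 units against 2379 in kidney).

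In all, 1049 of 16884 measured genes were higher in renal pelvis and 667 lower (61.1% higher), 252 and 83 of them by 4-fold, and bounds added 286 and 66. Scaled on the spike-in controls, 1458 were higher and 419 lower (77.7% higher). With normexp background correction these were 525 and 411, with list medians of 0.92 for B cells, 0.93 for T cells, 0.12 for cytotoxic and NK cells and 0.39 for the cell cycle. Junction and housekeeping medians were 0.63 and 0.036 with spike-in scaling.

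Between tissues of MRL/lpr mice, urothelial genes again marked the renal pelvis, fewer of them at 2-fold, and kidney genes lay further down there than in MRL/MpJ mice. Krt15 (8.49), Krt14 (7.99), Krt5 (7.34), Upk2 (7.09), Upk1b (6.95) and Upk3a (6.86) were among the 10 highest, with the gasdermin genes Gsdmc3 (6.60) and Gsdmc2 (6.03) and the ion transport regulator gene Fxyd3 (5.62). Sprr2a3 (8.74) was the highest of genes above background on both arrays. On the renal pelvis array alone were Foxa1 (at least 6.63), Sprr2f (6.29), the antibacterial lectin gene Reg3g (5.84) and the ceramide synthase gene Cers3 (5.74). Umbrella cell genes were higher in 9 of 10 cases (median 4.42 (3.01 to 6.86)) and basal and intermediate genes in 11 of 16 (median 2.10 (0.93 to 5.96)).

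Of the T cell genes 19 of 20 were higher in renal pelvis (median 1.78 (1.56 to 1.90); Cd2 2.10, Ctla4 2.04, Icos 1.99), and of the B cell genes 12 of 15 (median 2.18 (2.03 to 2.59); Spib 2.67). Plasma cell genes were higher in 10 of 13 cases (median 1.99 (1.07 to 2.25); Mzb1 2.54) and lymphoid structure genes in 11 of 16 (median 1.68 (1.01 to 2.04); Ltb 2.47, Ccl21a 2.32). Cell cycle genes were higher in 13 of 14 (median 1.44 (1.28 to 1.52); Mki67 1.73). Counts and medians were 6 of 12 and 1.18 (0.80 to 1.57) for cytotoxic genes, 6 of 11 and 1.32 (-0.078 to 1.70) for dendritic cells and 9 of 18 and 0.91 (0.47 to 1.14) for macrophages. They were 6 of 16 and 0.84 (-0.51 to 1.42) for inflammatory chemokines (Ccl20 2.84, Cxcl1 -2.20) and 4 of 13 and 0.90 (0.64 to 1.07) for inflammatory cytokines (Ifng 1.97). Class II genes stood at 3 of 9 higher (median 0.69 (0.46 to 2.21)) and adhesion genes at 4 of 9 (median 1.01 (0.46 to 1.70)). Neutrophils (0.42), type I interferon-stimulated genes (0.40), complement (-0.051), toll-like receptors (0.57) and antimicrobial genes (0.056; Saa3 2.77) had smaller medians.

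Proximal tubule genes were lower in renal pelvis in 15 of 21 cases (median -1.98 (-2.73 to -1.13); Slc22a8 -3.83, Slc22a6 -3.41), and distal convoluted tubule genes in 7 of 7 (-2.58 (-3.15 to -2.35); Slc12a3 -3.15). Intercalated cell genes were lower in 10 of 11 (-2.23 (-3.81 to -1.19); Slc26a4 -4.55, Hmx2 -4.09) and podocyte genes in 6 of 12 (-1.05 (-2.08 to -0.32); Nphs1 -2.20). Fatty acid oxidation genes were lower in 11 of 16 (-1.25 (-1.79 to -0.90); Cyp4a14 -2.88) and male kidney metabolism genes in 8 of 14, with 1 higher (-1.41 (-2.30 to -0.48)). Loop of Henle stood at -0.34 (-0.74 to 0.028), principal cells at -0.54 (-1.08 to 0.19) (Hsd11b2 -1.97), junctions at -0.43 (-0.72 to -0.16), mesangium at -0.90 (-1.45 to 0.62) and endothelium at -0.88 (-1.25 to -0.43). The oxoglutarate receptor gene Oxgr1 (-4.02), the vitamin D activating enzyme gene Cyp27b1 (-3.87), Mbl2 (-4.02) and Bhmt (-3.91) were among the lowest. Lymphatic endothelium had a median of 1.39 (0.84 to 2.18), matrix 0.58 (0.059 to 1.20) (Lum 2.99), smooth muscle 0.65 (-0.11 to 1.48) and adipocytes 0.90 (-0.15 to 1.60) (Adipoq 1.71). Kidney injury stood at 0.32, nerve at 0.20 (Ngfr 2.24), adrenal cortex at 0.20, red cells at 0.21 and housekeeping genes at 0.029.

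In all, 1437 of 17187 measured genes were higher and 1515 lower (48.7% higher), 261 and 295 of them by 4-fold, and bounds added 234 and 135. Scaled on the spike-in controls, 1918 were higher and 1081 lower (64.0% higher). With normexp background correction these were 922 and 991, with medians of 2.90 for umbrella cells and 0.59 for inflammatory cytokines. Red cell and housekeeping medians were 0.41 and 0.23 with spike-in scaling.

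**Figure D3:**
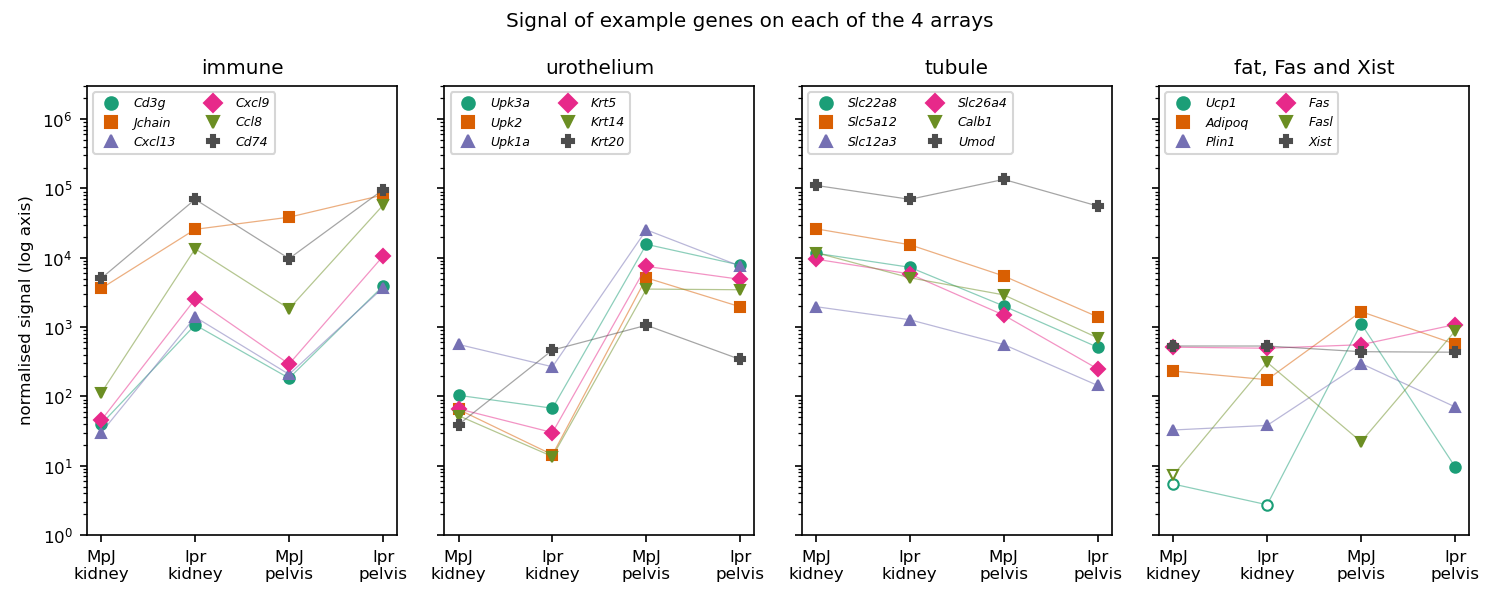
Normalised signal (vertical log axis) of example genes on each of the 4 arrays (horizontal axis), with open symbols where a probe was not above background. Cd3g stood at 39.8, 1073, 183 and 3899 units and Upk3a at 104, 67.4, 15606 and 7824 on the MRL/MpJ kidney, MRL/lpr kidney, MRL/MpJ renal pelvis and MRL/lpr renal pelvis arrays.

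The tissue differences of the 2 strains had a Pearson r of 0.76 and a Spearman rho of 0.66 over 16558 genes, with 603 higher genes shared of 1017 and 1135 (69.7 if independent) and 501 lower genes shared of 631 and 1501 (57.2). Spread between spots within an array was small beside the 2-fold rule: probes spotted 10 times on an array had a median SD of 0.040 to 0.044 log2 units. This leaves out any technical spread between arrays. Different probes of a gene were less alike. For genes counted at 2-fold with a second probe above background, that probe had the same direction in 92.3% (strain, kidney), 95.8% (strain, renal pelvis), 89.8% (tissue, MRL/MpJ), 94.5% (tissue, MRL/lpr) and 90.0% (strain difference between tissues). It was itself at least 2-fold the same way in 67.7%, 72.2%, 61.3%, 66.0% and 37.5%. Spread between mice, and between arrays of the same pool, was not measured.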

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

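Among the tests given here, those of array scaling and of brown fat were chosen before their result was seen, and the others after it. Krt20 was higher on the MRL/lpr array in kidney (3.57) and lower in renal pelvis (-1.64), and Igfbp2 likewise (1.01 and -1.25). They were picked out because the strain difference had opposite directions in the 2 tissues. That difference was not tested, as there was 1 array per group. A further 151 probes without a gene name were above background on both MRL/lpr arrays and on neither MRL/MpJ array, a signal in probes outside the comparisons of genes.

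Y-linked probes lay at background and Xist was bright on all 4 arrays, although the mice were labelled male. Whether the Y-linked probes work was not decided by Xist, above background on 4 arrays, since its signal is part of the pattern. Against female mice in all 4 pools stood 1 of 13 Y-linked probes, a Kdm5d probe above background on all 4 arrays while 5 other Kdm5d probes were not. The first form of this test asked for no such probe. It was changed, after that probe had been seen, to ask for at least 50% of the probes of a gene. None of the 4 Y-linked genes reached that. Of 23 probes placed on chromosome Y, 1 was above background on all 4 arrays. With the bright Xist, these values argue against pools of male mice only. Cross-hybridisation of the Kdm5d probe was not tested, so whether all 4 pools were female stays open.

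Nephron segment lists lay lower on the MRL/lpr arrays, and further below in renal pelvis than in kidney. Dilution by infiltrating cells alone would lower podocyte and proximal tubule genes alike, yet in kidney the podocyte median lay 0.93 above the proximal tubule median. Scaling of the arrays did not remove the pattern, since the highest proximal tubule median in renal pelvis over 4 scalings was -1.62. Less kidney tissue in the MRL/lpr renal pelvis dissection alone would not lower umbrella cell genes, yet their median there was -1.34. This covers umbrella cell genes only. Basal and intermediate urothelial genes lay lower by less (-0.60 (-0.95 to -0.18)), with 12 of 16 within 2-fold. In kidney RNA the umbrella cell median was -0.82 (-1.47 to 0.28). A loss of tubule expression in MRL/lpr mice and a mixture of these causes stay open, the former untested.

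Adipocyte genes and Ucp1 were bright on the MRL/MpJ renal pelvis array. A defect of single spots was argued against by probes in other spots: 9 of 10 further probes for 5 adipocyte genes, none of them for Ucp1, were at least 2-fold lower on the MRL/lpr renal pelvis array. For brown fat dissected with the MRL/MpJ renal pelvis, the median of a later brown fat list was 0.32 (-0.21 to 1.95) over MRL/MpJ kidney, below the 0.5 set beforehand as evidence against it, and 1.20 over MRL/lpr renal pelvis, past the 1 it needed. The interval of the former, taken into account only afterwards, reached above 0.5, so the test was read as undecided. Brown fat in the dissection and a strain difference in fat itself (adipocyte median in kidney -0.27) cannot be told apart with 1 pool per strain and tissue.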

How the results depend on the processing

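The spike-in scaling and the raising of values to the array floor were chosen after the data had been seen, and all other alternatives before. All 894 named gene differences stayed near their value under quantile normalization, the 75th percentile over probes above background on all 4 arrays and spike-in scaling. Under normexp background correction 562 did, 326 moved by more than the spread between probes and 6 turned sign. With the mean of a gene's probes 798 did and 96 moved. Spike-in scaling and the other percentile base shift all genes of a comparison by 1 common amount. As that amount was below the spread between probes, no named gene could move there. Their result was fixed by construction and says nothing about single genes. Of 200 list medians 170 stayed within their spread under normexp, 187 under spike-in scaling, 193 under quantile normalization and 195 under the other percentile base. All stayed with the mean of probes, with all members, with members above background on all 4 arrays and with values raised to the floor. No list median whose interval excluded 0 changed sign, except housekeeping genes between MRL/MpJ tissues under spike-in scaling. The Pearson r of the strain differences was 0.78 with genes above background on at least 1 array. Correction by normexp with an offset of 50 shrinks differences of dim probes by its construction. Under spike-in scaling and the other percentile base, list medians and counts moved through the common shift alone. Between MRL/MpJ tissues, spike-in scaling took the median gene from -0.094 to 0.13. In the remaining cases where a value moved, the cause was not tested. Signal over background limits the dim genes: 63.8%, 64.5%, 65.4% and 69.0% of probes were above it on the MRL/MpJ kidney, MRL/lpr kidney, MRL/MpJ renal pelvis and MRL/lpr renal pelvis arrays. A slide block was not run, since all 4 arrays lay on 1 slide. No paired analysis was possible within any of the 5 comparisons because each group had 1 array. Across them, a fit of strain and tissue effects over the 4 arrays, without their interaction, was possible with 1 residual degree of freedom. It was not run, since it takes the strain difference between tissues as noise.

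Gene counts rose without a filter on dim probes, which adds genes by construction. Strain in kidney: 1933 higher and 981 lower. Strain in renal pelvis: 2631 higher. Tissue in MRL/MpJ: 1978 higher and 1330 lower. Tissue in MRL/lpr: 2293 higher and 2305 lower. Strain difference between tissues: 1384 higher and 1881 lower. Counts at 4-fold, a stricter rule by construction, were as given here. Strain in kidney: 485 higher and 17 lower. Strain in renal pelvis: 828 higher and 159 lower. Tissue in MRL/MpJ: 252 higher and 83 lower. Tissue in MRL/lpr: 261 higher and 295 lower. Strain difference between tissues: 36 higher and 39 lower. Counts moved under normexp as follows. Strain in kidney: 128 lower. Strain in renal pelvis: 1540 lower. Tissue in MRL/MpJ: 525 higher and 411 lower. Tissue in MRL/lpr: 922 higher and 991 lower. Strain difference between tissues: 216 higher and 206 lower. A lower count moved under spike-in scaling. Tissue in MRL/MpJ: 419 lower.

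List medians moved under normexp. Between strains in kidney: T cells 2.83, cytotoxic and NK cells 1.87, inflammatory cytokines 0.88, type I interferon-stimulated genes 1.42 and cell cycle 0.97. Between strains in renal pelvis: T cells 3.52, neutrophils 0.52, cytotoxic and NK cells 2.64, inflammatory cytokines 1.22, loop of Henle -1.14, distal convoluted tubule -1.17, adipocytes -1.59 and cell cycle 1.77. Between MRL/MpJ tissues: T cells 0.93, B cells 0.92, macrophages 0.68, cytotoxic and NK cells 0.12, uroplakins and umbrella cells 3.65 and cell cycle 0.39. Between MRL/lpr tissues: B cells 1.78, inflammatory cytokines 0.59, uroplakins and umbrella cells 2.90, distal convoluted tubule -2.31, red cells 0.25 and cell cycle 1.14. Strain difference between tissues: T cells 0.77, B cells 0.66, neutrophils 0.27, loop of Henle -0.48 and cell cycle 0.74. Values of at least 1 log2 unit turned sign under normexp, that of Slc36a2 from a gene counted at 2-fold and the others from genes above background on 1 array of their comparison. Between strains in renal pelvis: Mc2r -0.18. Between MRL/MpJ tissues: Klrb1c -0.038. Between MRL/lpr tissues: Csf2 -0.11, Ucp1 -0.11 and Elovl3 -0.061. Strain difference between tissues: Slc36a2 0.047.

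List medians moved under quantile normalization. Between strains in kidney: proximal tubule -0.59, loop of Henle -0.49, red cells -0.053 and fatty acid oxidation and peroxisome -0.30. Between strains in renal pelvis: MHC class II 3.21 and loop of Henle -1.13. Between MRL/MpJ tissues: red cells 0.80. They moved with the other percentile base. Between strains in kidney: loop of Henle -0.58, cell cycle 1.95 and fatty acid oxidation and peroxisome -0.44. Between MRL/MpJ tissues: red cells 0.77. Between MRL/lpr tissues: red cells 0.24. They moved under spike-in scaling. Between strains in kidney: proximal tubule -0.88, intercalated cells -0.79 and red cells -0.28. Between MRL/MpJ tissues: epithelial junctions 0.63, lymphatic endothelium 1.89, red cells 0.93 and housekeeping 0.036. Between MRL/lpr tissues: T cells 1.98, inflammatory cytokines 1.10, type I interferon-stimulated genes 0.60, red cells 0.41, cell cycle 1.64 and housekeeping 0.23.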

Other observations

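These genes and probe sets were chosen after their values were seen. A set of 46 genes lay lower by at least 1.5 log2 units on the MRL/lpr arrays of both tissues, led by Igfbp5 (-4.22 and -4.74), given as kidney and renal pelvis values. It held the neighbouring organic anion transporter genes Slc22a26 (-2.17 and -3.1), Slc22a27 (-1.75 and -2.76), Slc22a28 (-2.05 and -3.01), Slc22a29 (-1.51 and -2.83) and Slc22a30 (-1.79 and -2.85), whose probes may cross-hybridise. Others were the growth factor gene Igf2 (-1.94 and -2.41), the histamine-making enzyme gene Hdc (-1.81 and -2.92) and Corin (-1.85 and -2.45), whose product cleaves natriuretic peptide precursors.

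The brown fat list, written after the adipocyte signals were seen, had medians of 0.32 (-0.21 to 1.95) between MRL/MpJ tissues and -1.20 (-1.46 to -0.43) between strains in renal pelvis. It stood at -0.35 (-0.60 to -0.14) between strains in kidney, -0.20 (-0.70 to 0.54) between MRL/lpr tissues and -0.66 (-1.19 to -0.32) for the strain difference between tissues. Adrb3, the adrenaline receptor gene of fat cells, was higher in MRL/MpJ renal pelvis than kidney (2.77) and lower on the MRL/lpr renal pelvis array (-1.84), and Cox8b stood at 1.98 in the former.

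Of 12662 probes without a gene name, 5831 were above background on all 4 arrays and 53 on both MRL/MpJ arrays alone. In both tissues, 166 of them were at least 4-fold higher on the MRL/lpr arrays and 2 at least 4-fold lower.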
